A study of Mus musculus with 12 samples.

How the data were processed

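Gene expression was measured by RNA sequencing in 12 libraries of embryonic mouse retina at E12.5. Each of 3 genotypes had 4 libraries. Per the labels, embryos came from single-night matings, retinas were freed of surrounding tissue and flash frozen, RNA was purified on spin columns, polyadenylated RNA was selected, and directional libraries of all samples were made and sequenced together. The labels call the libraries biological replicates, do not say how many embryos or eyes went into each, and do not say that replicates came from separate animals or litters, so p-values measure the spread between these samples.

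The deposited values are counts of reads per gene, whole numbers that the authors did not normalise, with 1 count column per library. Per the submitters' processing notes, the tools were bcl2fastq, FastQC, Trim Galore, STAR and HTSeq, and the genome build was mm10, also called GRCm38. The versions of these tools, the annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene, antisense genes and members of families with near-identical copies are uncertain. The counter's 5 lines for reads with no gene, ambiguous, low-quality, unaligned or multiply aligned reads held 23.9% to 27.9% of all counts in a library and were left out of library sizes and tests. Of the 53715 gene identifiers in the deposited count tables, 53620 matched the GENCODE M21 annotation of GRCm38, from which symbols and positions were taken.

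The 3 comparisons were orJ against control, orJ_mi against orJ and orJ_mi against control. All 12 libraries entered a single model of group means, because age, tissue, preparation and sequencing were shared, which left 9 residual degrees of freedom. Genes passed edgeR's expression filter with its minimum count of 10, which kept 17573. Library sizes were scaled by the trimmed mean of M values, and each gene was tested with edgeR's quasi-likelihood test with robust estimation, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Levels are in CPM, gene counts relative to the scaled library sizes, given as mean ± SD over the 4 libraries of a group. The standard error (SE) of a log2 fold change was taken from the fold change and the test statistic. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

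Gene lists were written from textbook knowledge: 30 lists with 593 entries, covering pigment, retinal pigment epithelium, lysosome, retinal progenitor, neurogenic, ganglion cell, photoreceptor and horizontal cell, ciliary margin, optic stalk, cell cycle, regulators of the G1 phase, the Notch, FGF, Wnt, BMP, Hedgehog and retinoid pathways, p53 targets, hypoxia and glycolysis, immediate early genes, a focus list of regulators the study's alleles bear on, and markers of lens, periocular mesenchyme, endothelium, erythroid cells, macrophages, neural crest, surface ectoderm, diencephalon and sex. Each list was tested with camera against the other genes at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. Of the 38 list calls made with the preset correlation, 17 held with an estimated correlation. The lysosome list was written of lysosome and V-ATPase genes of the network of Mitf and its relatives. It does not stand for lysosomes at large.

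The groups, the tests, the alternatives to the processing, the gene lists and the rule for naming genes were fixed before the data were examined. Named genes were all tested members of the focus list, the 8 genes with the largest rise and the 8 with the largest fall in each comparison, up to 4 called members with the smallest p from each list that passed camera or had at least 3 called members, and called markers of other tissues. The largest changes were taken among called genes with a mean log2 CPM of at least 1, no overlap between the 4 libraries of each group, and a symbol that is not a clone or predicted name. All genes named outside this rule were chosen after their values were seen.

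Depth was 23602725 to 33629575 gene counts per library, and 23222 to 25704 genes had at least 1 count. Within groups, chi-square per gene between pairs of libraries lay between 8.56 and 49.9 over 18 pairs, where sampling noise alone gives about 1, so no library was a duplicate of another. The fit was tested on simulated data with 200 changed genes among 17573. For orJ against control it recovered 44.8% of genes changed 1.5-fold, 76.1% changed 2-fold and 89.4% changed 4-fold, with 4 false calls. In orJ_mi against orJ the shares were 53.7%, 80.6% and 86.4% with 3 false calls, and in orJ_mi against control 53.7%, 61.2% and 90.9% with 6. A simulated list changed 1.5-fold was called by camera, and 0 of 20 unchanged lists passed an unadjusted threshold of 0.05. The simulated genes varied independently, so false calls by camera in lists whose genes vary together were not tested.

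The return toward control counted genes called in orJ against control that were called again in orJ_mi against orJ, by direction. Both comparisons use the orJ libraries, so the counts were set beside 20 simulations of unchanged groups, 20 simulations that kept the orJ effect with no effect of the mi allele, and all 6 divisions of the orJ libraries that give each comparison its own pair. Alternatives were median-of-ratios scaling, DESeq2, limma-voom, no filter on low counts, a filter at 1 CPM in at least 4 libraries, the replicate number or the library number set as a block, only the 2 groups compared, a non-robust spread, a test against a 1.5-fold change, an adjusted p under 0.01 and leaving out each library. A fit without 4 libraries that stood apart and a fit with the level of Y-linked genes as a covariate were added after seeing the data. Sequence variants, splicing and reads without a gene were not analysed here.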

Results

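RNA was sequenced from 12 libraries of embryonic mouse retina at E12.5, in 3 groups of 4. Control retinas carried 1 copy of the orJ allele of Vsx2, the homeobox regulator of retinal progenitors, whose orJ allele has a premature stop in the homeodomain. The orJ group carried 2 copies of it. The orJ_mi group carried 2 copies of orJ and 1 copy of the mi allele of Mitf, the master regulator of pigment cells. The mi allele removes an arginine from the DNA-binding domain and acts as a dominant negative. Total gene counts per library were 33536818, 31346180, 23712996 and 26745478 in control, 32047892, 33629575, 26941172 and 23602725 in orJ, and 33042606, 28754088, 23825954 and 27923561 in orJ_mi. In a principal component analysis, the first component held 49.9% of the variance and placed control libraries at -67.34 to -57.43, orJ at 35.23 to 48.76 and orJ_mi at 16.21 to 24.82, and the second held 10.3%.

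**Figure D1:**
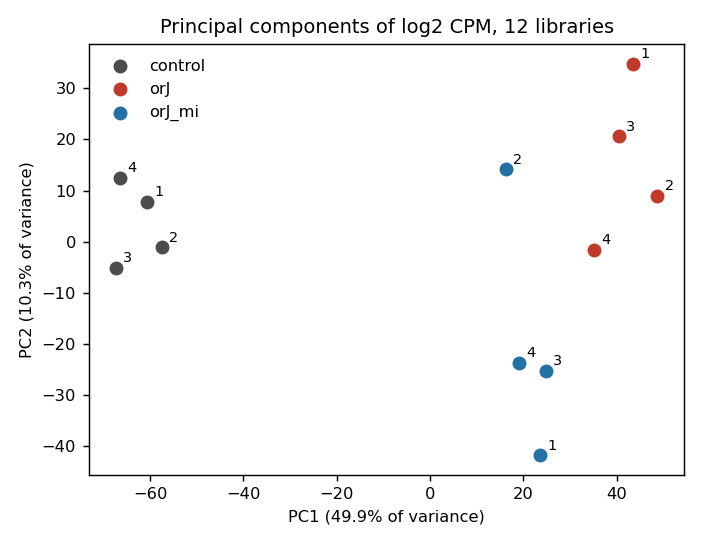
Principal components of log2 CPM over the 12 libraries, with the first component (49.9% of variance) on the horizontal axis and the second (10.3%) on the vertical axis, 1 point per library, coloured by group and numbered by replicate. The orJ_mi libraries lay between control and orJ on the first component, at 16.21 to 24.82.

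Several libraries stood apart within their group. Control 1 had 6.26% of its counts in ribosomal protein genes, against 3.83% to 4.68% in the other 11 libraries. Control 4 had 253 CPM of the immediate early gene Fos, against 0.172 to 0.387 in the other control libraries. Library orJ 4 had 65.5 CPM of the neuronal tubulin Tubb3, against 8.55 to 12.3 in the other orJ libraries. Library orJ_mi 1 had 87.2 CPM of the collagen Col1a1, against 9.96 to 20 in the other orJ_mi libraries. Both the X-inactivation transcript Xist and the Y-linked Ddx3y were present in 5 libraries, among them control 1 with 356 and 34.1 CPM, and orJ 1 and orJ 3 had Xist at 1177 and 1653 CPM. A fit without control 1, control 4, orJ 4 and orJ_mi 1, and a fit with the level of Y-linked genes as a covariate, were added after seeing these values. Ddx3y stood at 0.0311 and 0.11 CPM in orJ 1 and orJ 3 and at 18.2 CPM or more in all other libraries. The covariate therefore mainly sets orJ 1 and orJ 3 apart, and calls lost with it cannot be tied to sex.

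The targeted genes were read first. Vsx2 (ENSMUSG00000021239.12, chromosome 12, 84569762 to 84595457 on GRCm38) stood at 709 ± 25.9 CPM in control, 401 ± 73.4 in orJ and 353 ± 53.6 in orJ_mi (SD, n = 4). It fell in orJ against control (log2 fold change -0.82, SE 0.127, adjusted p = 0.000112) and did not pass in orJ_mi against orJ (-0.18, adjusted p = 0.534). Mitf (ENSMUSG00000035158.15, chromosome 6, 97807052 to 98021349) rose from 34.9 ± 2.82 CPM in control to 257 ± 7.58 in orJ, a log2 fold change of 2.88 (SE 0.0765, adjusted p = 1.14e-12). In orJ_mi it stood at 264 ± 20.9 CPM, with a log2 fold change of 0.04 against orJ (SE 0.0704, adjusted p = 0.877). Both alleles change the protein, so gene counts cannot verify the genotypes. CPM values below are means over the 4 libraries of a group, and adjusted p-values are from edgeR's quasi-likelihood test unless a list test is named.

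The comparison of orJ with control asks what the retina expresses without functional Vsx2. All 15 tested pigment cell genes rose, among them Rab27a, a small GTPase of melanosome transport (6.79 ± 1.52 to 85.3 ± 7.88 CPM), and Trpm1, a cation channel of pigment cells and bipolar neurons (173 ± 45 to 1848 ± 147). Of 20 neurogenic genes, 15 fell, among them Atoh7, the bHLH factor required for ganglion cell formation (697 ± 122 to 0.771 ± 0.283 CPM), and Neurog2, a proneural bHLH factor (105 ± 7.41 to 0.861 ± 0.399; SD, n = 4). Of 40 genes of DNA replication and mitosis, 38 fell, such as the DNA methylation factor Uhrf1, from 388 ± 35 to 203 ± 9.1 CPM. In total, 6806 of 17573 tested genes changed (38.7%), 3630 higher and 3176 lower in orJ, and 1960 of them by at least 2-fold (1358 higher, 602 lower). Tested against a 1.5-fold change, 1749 genes passed. The 4 orJ values lay all above or all below the 4 control values for 6313 genes (35.9%, where chance gives 2.86%).

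All 15 tested pigment genes rose in orJ, 15 when adjusted over the list alone (camera adjusted p = 6.53e-27). Rab27a (ENSMUSG00000032202.11, chromosome 9, 73044854 to 73097629) changed by 3.64 (SE 0.14), its melanosome partner Mlph by 3.08 (SE 0.158), Trpm1 by 3.42 (SE 0.156) and the ocular albinism receptor Gpr143 by 3.76 (SE 0.242). Of 24 lysosome genes, listed for a link to Mitf and its relatives, 22 rose and none fell, with the same counts adjusted over the list alone (adjusted p = 1.39e-18). They included the sulfatase Gns (1.69, SE 0.069), the mitochondrial coactivator Ppargc1a (1.64, SE 0.107), the hexosaminidase subunit Hexa (1.20, SE 0.0837) and the cathepsin Ctsa (1.16, SE 0.0844). The retinal pigment epithelium list had 13 of 17 genes higher and 0 lower, and 13 higher and 1 lower adjusted over the list alone (adjusted p = 8.44e-16). Among them Tfec, a Mitf relative, rose from 3.09 to 69.7 CPM (4.48, SE 0.132), and the homeobox gene Otx1 from 138 to 337 CPM (1.28, SE 0.0863). Tfeb, also of this family, rose by 1.10 (SE 0.151), while Tfe3 stood at 45.4 and 48 CPM (adjusted p = 0.324).

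The neurogenic list had 15 of 20 genes lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 2.85e-18). Atoh7 (ENSMUSG00000036816.4, chromosome 10, 63099651 to 63101279) changed by -9.86 (SE 1.01, adjusted p = 4.33e-05) and Neurog2 by -6.96 (SE 0.635). The Notch ligands Dll1 and Dll3 changed by -4.68 (SE 0.285) and -5.23 (SE 0.413), the latter by -6.13 without orJ 4, Hes6 by -1.92 and Rgs16 by -2.17. The member that rose was Otx2 (0.63, SE 0.145, adjusted p = 0.00404), a regulator of photoreceptors and pigment epithelium. Of 31 ganglion cell genes, 21 fell and 1 rose, and 23 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.72e-10, adjusted p = 0.221 with an estimated correlation). Lower were Stmn4 (-2.57, SE 0.132), the axonal adhesion molecule Cntn2 (-1.99, SE 0.153) and Klf7 (-1.04, SE 0.101), and higher was Rbpms, an RNA-binding protein (1.45, SE 0.137). The photoreceptor, horizontal and amacrine list had 10 of 15 genes lower and 3 higher, the same adjusted over the list alone (camera adjusted p = 9.46e-05). Lower were Onecut2 (-4.29, SE 0.157), Onecut3 (-5.39, SE 0.444) and Barhl2 (-6.45, SE 0.438, and -7.33 without orJ 4), and the retinoid receptor Rxrg rose from 3.36 to 118 CPM (5.13, SE 0.127). In orJ 4 the neurogenic list had a mean log2 CPM of 2.64, against 0.817 to 1.05 in the other orJ libraries.

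Of 40 cell cycle genes, 38 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 1.54e-24). Uhrf1 changed by -0.93 (SE 0.0686), the S-phase factor E2f1 by -1.13 (SE 0.0854), cyclin gene Ccna2 by -0.77 (SE 0.0575) and the spindle gene Tpx2 by -0.72 (SE 0.0584). Regulators of the G1 phase went both ways, with 2 of 18 higher and 7 lower, 2 and 8 adjusted over the list alone (adjusted p = 0.18). Cyclin D1, Ccnd1, fell from 570 ± 87 to 288 ± 36.6 CPM (-0.99, SE 0.12, adjusted p = 1.01e-05) and the inhibitor Cdkn1c rose by 1.27 (SE 0.151), while Rbl1 and Rb1 fell by 0.54 and 0.68 on the log2 scale. Another inhibitor, Cdkn1b, was at 141 and 126 CPM (-0.16, SE 0.0659, adjusted p = 0.063), with adjusted p = 0.0449 without control 2, 0.0188 without orJ 1 and 0.0424 to 0.0443 with median-of-ratios scaling, DESeq2, the stricter filter or the Y-linked covariate. The progenitor list had 7 of 27 genes higher and 14 lower, the same adjusted over the list alone (camera adjusted p = 0.00618, lower, adjusted p = 0.519 with an estimated correlation), and 13 of its members stood in another list. Sox2 fell by 1.18 (SE 0.1) on the log2 scale, Gas1, a Hedgehog co-receptor, rose by 1.70 (SE 0.101), Pax6 rose by 0.52 (SE 0.0754), and Rax stood at 297 and 267 CPM (adjusted p = 0.413).

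FGF pathway genes were lower, with 12 of 22 lower and 1 higher, 12 and 2 adjusted over the list alone (camera adjusted p = 0.00109, adjusted p = 0.384 with an estimated correlation). The ligands Fgf15, Fgf9 and Fgf3 changed by -2.32 (SE 0.154), -2.33 (SE 0.111) and -4.92 (SE 0.282), and the receptor Fgfr2 rose by 1.92 (SE 0.0746). The Notch list had 5 of 28 genes higher and 10 lower, the same adjusted over the list alone (camera adjusted p = 0.00691, lower, adjusted p = 0.221 with an estimated correlation). Its effector Hes5 fell from 28.5 to 0.813 CPM (-5.16, SE 0.385) and the modulator Lfng by 2.59 (SE 0.291) on the log2 scale, while Hes1 stood at 172 and 165 CPM (adjusted p = 0.709). The focus list of 16 regulators had 7 higher and 5 lower, 7 and 6 adjusted over the list alone, with a median log2 fold change of 0.0112, a mean of -0.149 and camera pointing higher (adjusted p = 0.00109, adjusted p = 0.0946 with an estimated correlation). In this list 14 genes stood in other lists.

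Ciliary margin genes rose, 8 of 15 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 6.44e-07). Higher were the gap junction gene Gja1 (1.99, SE 0.0859), the Wnt secretion factor Wls (9.97 to 99.8 CPM, 3.32, SE 0.141) and Col9a1 (1.09, SE 0.0859), and lower were Sfrp2 (-0.70, SE 0.13), Tcf7l2 and, chosen after its values were seen, Wfdc1. Tcf7l2 changed by -0.31 (adjusted p = 0.0174, and 0.0579, 0.0593 and 0.0861 without control 4, without orJ 2 and with the Y-linked covariate). Wfdc1 changed by -0.29 (adjusted p = 0.0237), by -0.19 without control 1 and by -0.15 without the 4 libraries that stood apart (adjusted p = 0.227). Its adjusted p was 0.0545 to 0.0642 without control 1 or orJ 1, 2 or 4. The list shared 9 of its genes with other lists. In the Wnt list, 11 of 25 genes rose and 4 fell, 12 and 4 adjusted over the list alone (camera adjusted p = 0.00776, adjusted p = 0.251 with an estimated correlation). Axin2, a feedback target of Wnt signalling, rose by 1.39 (SE 0.0899), Sfrp1 by 1.31, Tcf7 by 0.90 and Rnf43 by 2.49. Lists that did not pass camera held called genes as well. The BMP list had 10 of 24 higher and 3 lower, 10 and 4 adjusted over the list alone (adjusted p = 0.0849), among them Bmp4 (1.00, SE 0.145), Bmp7 (0.93, SE 0.0888), Bmp2 (1.72) and Smad9 (0.97). The retinoid list had 10 of 18 higher and 3 lower, 11 and 4 adjusted over the list alone (adjusted p = 0.18), with Stra6 (0.97) and Rlbp1 (2.63) higher and Crabp1 (-2.93) and the retinaldehyde dehydrogenase Aldh1a3 (443 to 220 CPM, -1.01, SE 0.164) lower. The optic stalk list had 1 of 7 higher, Pax2 (0.53, with adjusted p = 0.0604 without a filter and 0.0597 with the Y-linked covariate), and 3 lower, the homeobox genes Vax1 (-2.69, and -3.28 without orJ 4) and Vax2 (-1.52) and the forebrain factor Foxg1 (-0.93), at adjusted p = 0.0656.

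Counts were the same when adjusted over the list alone for 5 further lists that did not pass. Hypoxia and glycolysis genes were 2 of 20 higher and 8 lower (adjusted p = 0.18), with the glucose transporter Slc2a1 (-0.82) and Eno1 (-0.43) lower and Pdk1 (1.00) and Aldoc (1.72) higher. Hedgehog genes were 1 of 11 higher (adjusted p = 0.212), p53 targets 4 of 16 higher and 2 lower (adjusted p = 0.652), and diencephalon genes 1 of 12 higher, Emx2 (3.37, 2.48 without orJ 4, and adjusted p = 0.0679 with limma-voom), and 1 lower (adjusted p = 0.683). Immediate early genes were 6 of 16 lower and 0 higher (adjusted p = 0.18), among them Klf6 (-0.69, SE 0.115) and Dusp1 (-1.73). The change of Dusp1 was -0.79 without control 4, and its adjusted p was 0.0503 to 0.0655 without each orJ library in turn. It was 0.0704 with limma-voom, 0.0826 with the replicate number as a block, 0.0791 with only the 2 groups compared and 0.0951 with the Y-linked covariate. In control 4, Dusp1 stood at 127 CPM against 23.9 to 29.7 in the other control libraries.

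Markers of tissues outside the retina were measured in the same libraries. Periocular mesenchyme genes were higher in orJ for 14 of 19 and lower for 0, 15 and 0 adjusted over the list alone (camera adjusted p = 0.00109, adjusted p = 0.567 with an estimated correlation). None of these genes stood in another list, and 15 reached 1 CPM in control. Their mean log2 CPM was 1.86 ± 0.321 in control, 3.83 ± 0.575 in orJ and 3.88 ± 1.09 in orJ_mi, beside the rise of the pigment, ciliary margin and Wnt lists. Eya1 rose by 2.03 (SE 0.188), Pitx2 from 2.33 to 18.6 CPM, Foxc1 from 2.61 to 16.2 (adjusted p = 0.0594 with limma-voom). Col3a1 rose from 11.2 to 54.2 (adjusted p = 0.0715 without the 4 libraries that stood apart). Col1a1 rose from 3.9 to 24 CPM (adjusted p = 0.0318, 0.0522 to 0.0894 without orJ 2 or any control library, 0.0959 with limma-voom and 0.0557 without a filter). Endothelial markers were 8 of 19 higher and 1 lower, 11 and 1 adjusted over the list alone (adjusted p = 0.073). The lower gene was Kdr, a receptor also expressed by retinal progenitors (116 to 17.6 CPM). Pdgfrb rose by 1.29 (adjusted p = 0.0184, 0.0517 without orJ 2 and 0.0735 without the 4 libraries). Cdh5 rose by 1.49 (adjusted p = 0.0439), with adjusted p between 0.0509 and 0.11 without control 1, control 4, orJ 2, orJ 3, orJ 4, orJ_mi 3 or orJ_mi 4. Its adjusted p was 0.0821 without a filter, 0.072 with the replicate number as a block, 0.0619 with only the 2 groups compared and 0.188 without the 4 libraries. Surface ectoderm markers were 6 of 14 higher, among them Krt18 from 11.5 to 54.1 CPM (adjusted p = 0.18). Lens markers were 2 of 21 higher, among them Hsf4 by 2.40 (adjusted p = 0.924), and neural crest markers were 1 of 9 higher and 1 lower (adjusted p = 0.754). Hsf4 did not follow the lens gene Cryaa across orJ 1 to 4 (3.79, 4.29, 3.66 and 2.79 CPM, against 4.2, 3.77, 461 and 47.2). Erythroid markers were 0 of 14 higher and 0 lower (adjusted p = 0.212), macrophage markers 1 of 17 higher, 0 adjusted over the list alone (adjusted p = 0.697), and sex-linked genes 0 of 5 either way (adjusted p = 0.532). The sex list joins Xist with Y-linked genes, which go opposite ways with sex. Its test therefore cannot show that the groups were balanced for sex. The largest rises outside the lists were those of Dpp10 (5.19, and 5.84 without control 3), the opioid receptor Oprd1 (5.05), Wnt16 (4.55), Sntg1 (4.41) and Brinp1 (4.25). Pitx1 was higher by 6.14 (adjusted p = 0.0301), but by 2.23 without orJ 4, which had 37.6 CPM, and at adjusted p = 0.0652 to 0.0718 without any 1 control library. Its adjusted p was 0.274 with limma-voom (a change of 3.35), 0.0534 without a filter and 0.177 without the 4 libraries (a change of 1.95). It was 0.123 with the replicate number as a block and 0.0546 with the library set as a block. The largest falls were in neuronal genes, Insm2 (-8.02), Prdm8 (-7.38), the neuropeptide Gal (-7.28), Onecut1 (-7.25) and Mir124a-1hg (-7.03), and Pou4f2, a ganglion cell factor, stood at 29.4 CPM in control and 0.028 in orJ.

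**Figure D2:**
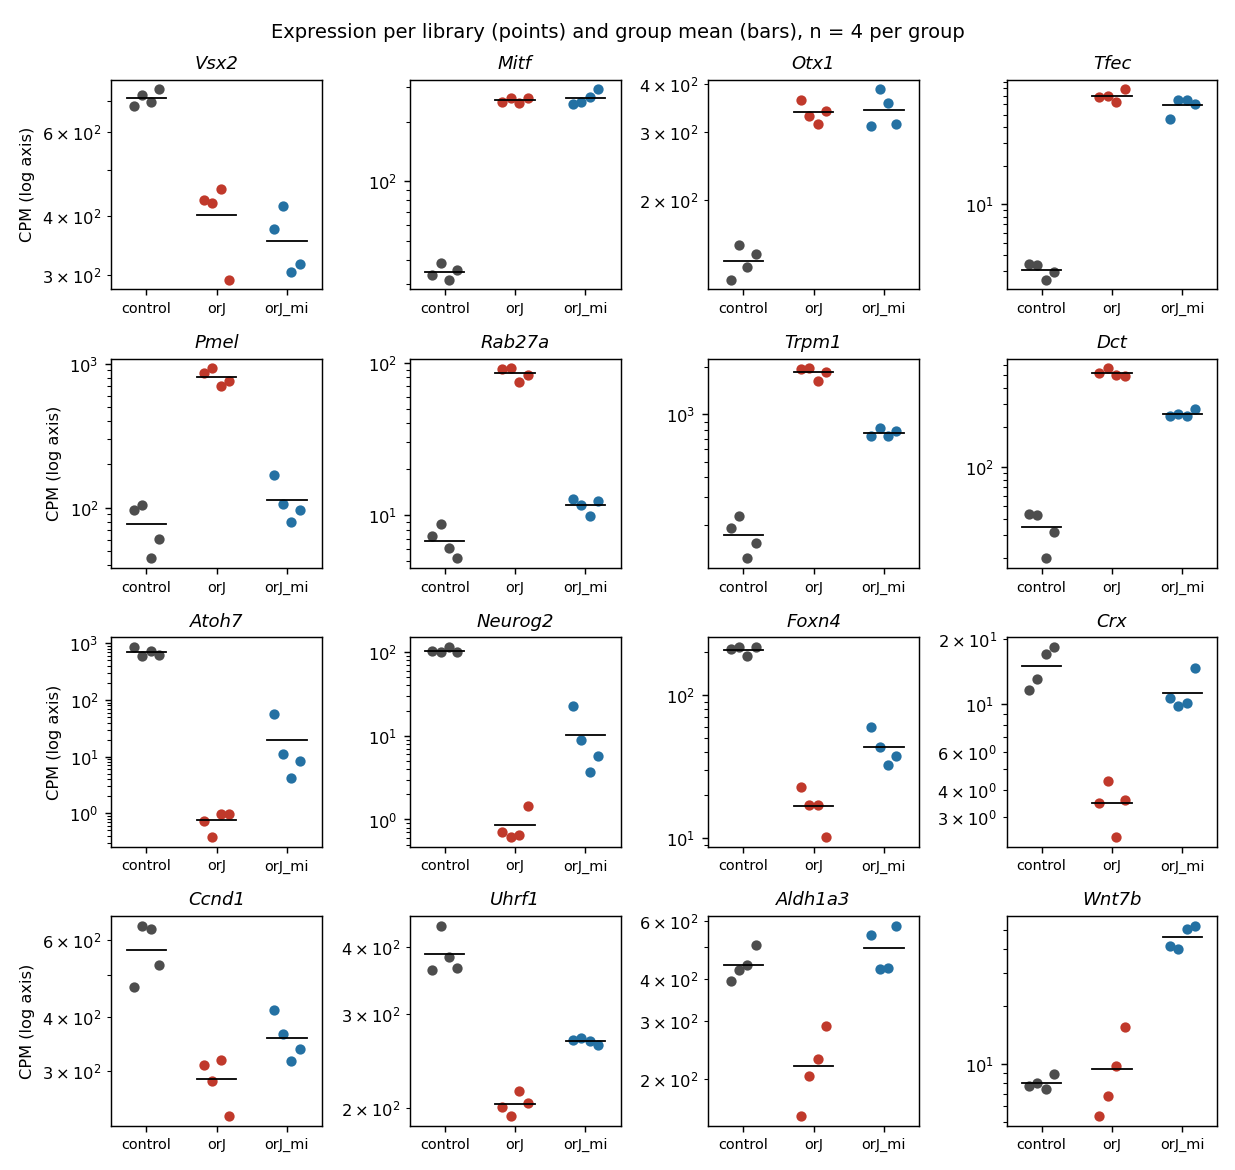
CPM per library on a log axis for 16 genes in control, orJ and orJ_mi, with 1 point per library (n = 4) and a bar at the group mean. Mean Rab27a was 6.79, 85.3 and 11.6 CPM and mean Uhrf1 388, 203 and 267 CPM in the 3 groups, while mean Mitf was 34.9, 257 and 264 CPM.

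The comparison of orJ_mi with orJ asks which genes move when the mi allele of Mitf is present in the orJ retina. Of 15 pigment genes, 12 fell, among them Rab27a from 85.3 ± 7.88 to 11.6 ± 1.26 CPM and Pmel (ENSMUSG00000025359.10, chromosome 10, 128704195 to 128720238), the fibril protein of melanosomes, from 814 ± 103 to 113 ± 38.6. Of 40 cell cycle genes, 12 rose (camera adjusted p = 1.72e-15 for the list, adjusted p = 0.092 with an estimated correlation), among them Uhrf1 from 203 ± 9.1 to 267 ± 3.33 CPM. Atoh7 was at 0.771 ± 0.283 CPM in orJ and 19.8 ± 24 in orJ_mi, and Neurog2 at 0.861 ± 0.399 and 10.3 ± 8.64 (SD, n = 4). In total 1039 of 17573 genes changed (5.91%), 361 higher and 678 lower in orJ_mi, and 248 by at least 2-fold (68 higher, 180 lower). With only the 2 groups compared 1608 genes changed, 667 of them higher. With DESeq2 654 genes were higher, and without the 4 libraries that stood apart, a choice made after seeing the data, 669 of 1573 were. The total was 649 without orJ 2 and 668 without orJ 1, 635 with Y-linked genes as a covariate (182 higher), 509 at an adjusted p under 0.01 and 127 tested against a 1.5-fold change. The number lower was 450 without orJ 2, and the number higher was 193 without orJ 1, 199 without orJ 2, 215 without orJ_mi 3 and 599 without control 1. The groups did not overlap for 2766 genes (15.7%, where chance gives 2.86%).

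In the pigment list, 12 of 15 genes fell and 0 rose, 14 and 0 adjusted over the list alone (camera adjusted p = 2.13e-61). The changes were -2.87 for Rab27a (SE 0.133, adjusted p = 7.47e-09), -2.85 for Pmel (SE 0.314), -2.73 for Mlph (SE 0.154), -3.96 for Gpr143 (SE 0.246) and -2.27 for Tyrp1, a melanin synthesis enzyme (SE 0.197). Tyr (-1.51, adjusted p = 0.109), Oca2 (-1.01, adjusted p = 0.0612) and Rab38 (-0.27, adjusted p = 0.423), chosen after their values were seen, did not pass. Tyr and Oca2 passed with DESeq2 (adjusted p = 0.0234 and 0.00332), limma-voom (0.036 and 0.00995), the library set as a block (0.00498 and 0.00743), without orJ_mi 1 (0.0162 and 0.00716) and without the 4 libraries that stood apart (0.0385 and 0.0302). Oca2 also passed without control 2 (0.0198) or control 3 (0.0464), and with only the 2 groups compared Oca2 (0.0387) and Rab38 (0.015) did. Of 24 lysosome genes, listed for a link to Mitf and its relatives, 14 fell and 0 rose, 19 and 0 adjusted over the list alone (camera adjusted p = 3.59e-21). Among them were Gns (-0.61, SE 0.0673), Hexa (-0.65, SE 0.0824), the endosomal tetraspanin Cd63 (-0.73, SE 0.0936) and the autophagy receptor Sqstm1 (-0.48, SE 0.0737). The pigment epithelium list had 4 of 17 lower and 0 higher, 5 and 0 adjusted over the list alone (camera adjusted p = 0.00225, adjusted p = 0.249 with an estimated correlation). Rlbp1, a retinoid carrier, changed by -1.48 (SE 0.208) and Bhlhe41 by -1.43 (SE 0.188). Ttr stood at 1.23 CPM in orJ and 0.0235 in orJ_mi, and Lrat fell by 1.38 (adjusted p = 0.0177, 0.061, 0.0543 and 0.0531 without orJ 4, orJ_mi 1 and orJ_mi 2, 0.0618 without a filter and 0.112 without the 4 libraries). Within the Mitf family, Tfec stood at 69.7 and 59.3 CPM (adjusted p = 0.278) and Tfe3 at 48 and 49.8 (adjusted p = 0.77). Tfeb changed by -0.57 (SE 0.148, adjusted p = 0.0323), with adjusted p from 0.0652 to 0.128 without orJ 1, orJ 2, orJ 3, orJ_mi 3 or orJ_mi 4 and 0.213 with the Y-linked covariate.

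The neurogenic list had 3 of 20 genes higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 4.42e-05, adjusted p = 0.401 with an estimated correlation, fry adjusted p = 0.122). Foxn4, a factor of horizontal and amacrine fate, rose from 16.7 to 43.4 CPM (1.37, SE 0.233, adjusted p = 0.00587). Neurog2 changed by 3.64 (SE 0.628, adjusted p = 0.00836) and by 2.90 without orJ_mi 1, and its adjusted p was 0.0569 with Y-linked genes as a covariate. Atoh7 changed by 4.74 (SE 0.964, adjusted p = 0.0205) and by 3.40 without orJ_mi 1, which had 55.5 CPM. Its adjusted p was 0.0707, 0.0768, 0.0572 and 0.0513 without orJ 1, 2, 3 and 4, 0.144 with limma-voom and 0.101 with the Y-linked covariate. The photoreceptor, horizontal and amacrine list had 2 of 15 higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.0166, adjusted p = 0.249 with an estimated correlation, fry adjusted p = 0.053). Its camera adjusted p was 0.164 without orJ_mi 1, 0.15 without the 4 libraries and 0.052 with the Y-linked covariate. The photoreceptor homeobox gene Crx rose from 3.48 to 11.3 CPM (1.69, SE 0.197) and Onecut2 by 0.81 (SE 0.151), and Rxrg fell by 0.62 (SE 0.0993) on the log2 scale. The ganglion cell list had 1 of 31 higher and 1 lower, 2 and 2 adjusted over the list alone (adjusted p = 0.396). In the optic stalk list Vax1 (1.55 to 8.8 CPM, 2.52, SE 0.382) and Vax2 (49.8 to 97.5, 0.97, SE 0.114) rose, 2 of 7 higher and 0 lower, 3 and 1 adjusted over the list alone (camera adjusted p = 0.000497).

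In the cell cycle list 12 of 40 genes rose and 0 fell, 25 and 0 adjusted over the list alone (camera adjusted p = 1.72e-15, adjusted p = 0.092 with an estimated correlation). Uhrf1 rose by 0.39 (SE 0.0682, adjusted p = 0.00213), Tpx2 by 0.29 (SE 0.0582) and the spindle checkpoint kinase Bub1b by 0.28 (SE 0.0577). Mki67, the proliferation antigen, rose by 0.35 (adjusted p = 0.0186), with adjusted p of 0.0535, 0.0604, 0.0538 and 0.0577 without orJ 1, orJ 4, orJ_mi 1 and orJ_mi 4, and 0.0508 with the Y-linked covariate. Ccnd1 was at 288 and 359 CPM (0.32, SE 0.119, adjusted p = 0.159). G1 regulators were 1 of 18 higher and 1 lower (adjusted p = 0.264), and the one that rose was Ccnd2, from 224 to 382 CPM (0.77, adjusted p = 0.00103; chosen after its values were seen). Progenitor genes were 3 of 27 higher and 3 lower (adjusted p = 0.212), with Gas1 (-0.46, SE 0.098) lower. Nr2e1 rose by 1.21 (adjusted p = 0.0176, 0.0659 and 0.0517 without orJ 1 and orJ 3, 0.055 without a filter and 0.101 with the Y-linked covariate). Tbx2 fell by 0.49 (adjusted p = 0.0182, 0.0521 to 0.0682 without orJ 1, orJ 2, orJ 3, orJ_mi 1 or orJ_mi 4, and 0.106 with the Y-linked covariate).

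Other lists did not pass in orJ_mi against orJ. In the retinoid list (adjusted p = 0.74), Aldh1a3 rose from 220 to 496 CPM (1.18, SE 0.165, adjusted p = 0.000778). Rxra changed by -0.29 (adjusted p = 0.0359), with adjusted p from 0.0677 to 0.124 without any orJ library or orJ_mi 2, 3 or 4. It was 0.05755 with the replicate number as a block and 0.0749 with the Y-linked covariate. In the BMP list (2 of 24 higher and 1 lower, 2 and 2 adjusted over the list alone, adjusted p = 0.852), Msx2 rose by 1.42 (SE 0.21) and Fst by 0.55 (SE 0.12, adjusted p = 0.0662 with the Y-linked covariate). Bmp2 changed by -0.82 (adjusted p = 0.0232, and 0.0551 to 0.0828 without orJ 2, orJ 4, orJ_mi 3 or orJ_mi 4). In the Wnt list (2 of 25 higher and 2 lower, 3 and 2 adjusted over the list alone, adjusted p = 0.356), Wnt5b rose by 0.46 (SE 0.0919). The antagonist Dkk1 rose by 0.97 (adjusted p = 0.0172, 0.0648, 0.0543 and 0.0525 without orJ 1, orJ_mi 3 and orJ_mi 4, 0.0666 without a filter and 0.0943 with the Y-linked covariate). Tcf7 changed by -0.35 (adjusted p = 0.0191, 0.0599 to 0.0757 without orJ 1, orJ 2, orJ 3, orJ_mi 1 or orJ_mi 3, and 0.111 with the Y-linked covariate). Rnf43 changed by -0.84 (adjusted p = 0.044), and its adjusted p was 0.0509 to 0.12 without control 2, control 4, any orJ library or orJ_mi 2, 3 or 4. It was 0.0589 with the replicate number as a block. Focus genes that did not pass included Otx1 (337 and 342 CPM), Otx2 (136 and 121), Pax6 (1239 and 1198), Rax (267 and 241), Fgf15 (75.2 and 77.7), Sfrp2 (1712 and 1914), Hes1 (165 and 160) and Cdkn1b (126 and 121). Of the tissue markers, Eya1 (-1.21, SE 0.181), Hsf4 (-1.50, SE 0.242) and Krt18 (-1.37, adjusted p = 0.0168, and 0.0552 and 0.0539 without orJ_mi 3 and orJ_mi 4) fell. In orJ_mi 1, Eya1 was at 13.6 CPM (others 12.8 to 18.8), where Col1a1 was at 87.2 (others 9.96 to 20). Hsf4 did not follow the lens gene Cryaa over the orJ libraries, so these falls cannot be read as less lens or mesenchyme. The mesenchyme list had 0 of 19 higher and 1 lower (adjusted p = 0.835). Gata3 was higher by 2.19 (adjusted p = 0.0232, and 0.0642 to 0.0853 without orJ 1, orJ 2, orJ 3 or orJ_mi 3). Its adjusted p was 0.226 with limma-voom, 0.0585 without a filter, 0.0535 with the replicate number as a block and 0.0664 with only the 2 groups compared. It was 0.176 with the Y-linked covariate and 0.142 without the 4 libraries.

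The largest falls in orJ_mi against orJ also included the water channel Aqp3 (-3.34, SE 0.386), the melanosomal glycoprotein Gpnmb (-3.20, SE 0.408), the PMEL-cleaving protease Bace2 (-2.93, SE 0.336), Islr2 (168 to 30.8 CPM, -2.45, SE 0.103) and the homeobox gene Gsx2 (-2.42, SE 0.229). Among the largest rises, Wnt7b (ENSMUSG00000022382.15, chromosome 15, 85535437 to 85582473) went from 9.36 ± 4.5 to 46.1 ± 6.37 CPM (2.31, SE 0.269, adjusted p = 0.000412), and the gene AU022754, which overlaps it, stood at 0.324 and 1.48 CPM. Grin2c, a glutamate receptor subunit, rose by 2.59 (SE 0.5, adjusted p = 0.0508 with the Y-linked covariate) and the keratin Krt90 by 2.09 (SE 0.331). Vmn2r2 was higher by 2.10 (SE 0.413), but it belongs to a family of near-identical receptors and its counts are uncertain. The muscle gene Neb was higher by 2.33 (adjusted p = 0.0328), by 1.51 without orJ_mi 3, and at adjusted p = 0.051 to 0.113 without control 2, any orJ library or orJ_mi 4. Its adjusted p was 0.173 with limma-voom, 0.0934 without a filter, 0.0886 with only the 2 groups compared, 0.219 with the Y-linked covariate and 0.163 without the 4 libraries.

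The comparison of orJ_mi with control gives the distance that remained with the mi allele present. Mitf and Tfec rose in orJ_mi by 2.92 (SE 0.0766) and 4.25 (SE 0.132), and Atoh7 fell from 697 to 19.8 CPM (-5.12, SE 0.75, and -6.47 without orJ_mi 1). Dct, a melanin synthesis enzyme, rose from 34.5 ± 11.1 to 255 ± 15.4 CPM and Trpm1 from 173 ± 45 to 767 ± 46.1, while Rab27a rose from 6.79 ± 1.52 to 11.6 ± 1.26 (SD, n = 4). In total 4677 of 17573 genes changed (26.6%), 2531 higher and 2146 lower in orJ_mi, and 1297 by at least 2-fold (883 higher, 414 lower). There were 2668 at an adjusted p under 0.01, and 860 tested against a 1.5-fold change. The groups did not overlap for 4563 genes (26%, where chance gives 2.86%).

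Of 15 pigment genes, 8 rose in orJ_mi against control and 1 fell, 9 and 1 adjusted over the list alone (camera adjusted p = 1.26e-07, adjusted p = 0.188 with an estimated correlation), with Dct at 2.88, Trpm1 at 2.15, Rab38 at 1.60 and Rab27a at 0.77. The gene that fell was Mlana (-1.33, adjusted p = 0.0467; chosen after its values were seen), with adjusted p from 0.0537 to 0.149 without any 1 library but control 4 or orJ_mi 1, 0.14 with limma-voom, 0.0996 with only the 2 groups compared and 0.0542 with the Y-linked covariate. Lysosome genes were 17 of 24 higher and 0 lower, 21 and 0 adjusted over the list alone (adjusted p = 9.62e-10), with Gns at 1.08 and Ppargc1a at 1.11. Pigment epithelium genes were 11 of 17 higher and 1 lower in either adjustment, over all genes or adjusted over the list alone (adjusted p = 4.6e-18), with Rlbp1 at 1.15. Ciliary margin genes were 9 of 15 higher and 1 lower, 9 and 2 adjusted over the list alone (adjusted p = 7e-12), with Gja1 at 1.70 and Wls at 2.66. Wnt genes were 14 of 25 higher and 2 lower, 15 and 4 adjusted over the list alone (adjusted p = 1.17e-05, adjusted p = 0.0621 with an estimated correlation), with Axin2 at 1.34, Tnfrsf19 at 1.27 and the ligand Rspo2 at 3.15. Hedgehog genes were 3 of 11 higher and 0 lower (adjusted p = 0.0225, adjusted p = 0.346 with an estimated correlation, 0.0958 without control 1 and 0.102 without the 4 libraries that stood apart). BMP genes were 7 of 24 higher and 1 lower, 8 and 3 adjusted over the list alone (adjusted p = 0.0243, adjusted p = 0.346 with an estimated correlation, and 0.0678 without control 2), with Bmp4 at 1.28 and Bmp7 at 0.88.

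Neurogenic genes were 16 of 20 lower and 1 higher in orJ_mi against control, 17 and 1 adjusted over the list alone (camera adjusted p = 2.67e-22), with Dll1 at -3.76 and Dll3 at -4.14. Ganglion cell genes were 24 of 31 lower and 1 higher, 25 and 1 adjusted over the list alone (adjusted p = 2.04e-15, adjusted p = 0.136 with an estimated correlation), with Stmn4 at -1.85 and Cntn2 at -2.04. Photoreceptor, horizontal and amacrine genes were 8 of 15 lower and 3 higher (adjusted p = 9.93e-05), with Onecut2 at -3.48. Cell cycle genes were 37 of 40 lower and 0 higher, also adjusted over the list alone (adjusted p = 1.82e-18), with E2f1 at -1.02, Ccna2 at -0.53, Uhrf1 at -0.54 and the topoisomerase Top2a at -0.56. Progenitor genes were 12 of 27 lower and 6 higher (adjusted p = 0.00401, adjusted p = 0.483 with an estimated correlation). FGF genes were 9 of 22 lower and 2 higher, 10 and 2 adjusted over the list alone (adjusted p = 0.000293, adjusted p = 0.346 with an estimated correlation), with Fgf9 at -1.46, Fgf3 at -4.34 and Fgfr2 at 1.68. Notch genes were 10 of 28 lower and 3 higher in either adjustment, with a median of 0.0401, a mean of -0.742 and camera pointing lower (adjusted p = 0.00132, adjusted p = 0.086 with an estimated correlation), and Hes5 changed by -4.70. The focus list was 7 of 16 higher and 6 lower (camera adjusted p = 4.15e-05, higher). Its called genes included Vsx2 (709 to 353 CPM), Otx1 (1.30), Pax6 (0.47), Gas1 (1.25), Fgf15 (-2.27), Sfrp2 (-0.54) and Ccnd1 (-0.67). Tfeb was higher by 0.53 (adjusted p = 0.0173, 0.0649 without orJ_mi 1 and 0.0632 without the 4 libraries that stood apart). Otx2 was higher by 0.46 (adjusted p = 0.0342), with adjusted p from 0.0578 to 0.115 without control 1, 2 or 3 or orJ_mi 2, 3 or 4 and 0.091 without a filter. Cdkn1b was lower by a log2 fold change of -0.22 (adjusted p = 0.0237), with adjusted p from 0.0523 to 0.0608 without control 3, control 4, orJ_mi 3 or orJ_mi 4, 0.0589 without a filter and 0.0503 without the 4 libraries.

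Mesenchyme markers were 17 of 19 higher in orJ_mi than in control and 0 lower, also adjusted over the list alone (camera adjusted p = 7.98e-06, adjusted p = 0.403 with an estimated correlation). Endothelial markers were 8 of 19 higher and 1 lower, 13 and 1 adjusted over the list alone (adjusted p = 0.00116, adjusted p = 0.573 with an estimated correlation). Without orJ_mi 1 the changes were smaller for Pitx2 (3.39, and 2.34 without it), Foxc1 (3.10 and 1.93), Col1a1 (3.04 and 1.83) and Foxc2 (4.32 and 2.79). Foxc2 had adjusted p = 0.0192, 0.051 and 0.0503 without control 1 and control 4, and 0.0755 with the replicate number as a block. Col1a1 had adjusted p = 0.0246, 0.0536, 0.0623 and 0.0643 without control 1, 3 and 4, and 0.0501 with only the 2 groups compared. Col6a3 changed by 4.34 (adjusted p = 0.0261), by 2.70 without orJ_mi 1 (adjusted p = 0.0574), and at adjusted p = 0.0527 to 0.0667 without any 1 control library. With limma-voom the adjusted p was 0.0573 for Pitx2, 0.0778 for Foxc1, 0.113 for Col1a1, 0.157 for Foxc2 and 0.194 for Col6a3. Without the 4 libraries that stood apart it was 0.0634 for Foxc1 (a change of 1.76), 0.203 for Col1a1 (1.71), 0.232 for Foxc2 (2.58) and 0.25 for Col6a3 (2.76). Diencephalon markers were 5 of 12 higher (camera adjusted p = 0.0745), among them Gata3 (2.31, with adjusted p = 0.0836 with limma-voom and 0.194 without the 4 libraries). Among the largest rises were the transcription factor Lmo3 (5.05, SE 0.178), Oprd1 (4.78), Rxrg (4.51), Dpp10 (4.74, and 5.38 without control 3) and the orphan receptor Gpr50 (4.29). The largest falls were in neuronal genes: the axon guidance ligand Slit1 (-6.05), Ina (-5.77), Ppp1r17 (-5.61), and, with the value without orJ_mi 1 given second, Gal (-6.43 and -8.42), Igfbpl1 (-6.00 and -7.65), Stmn2 (-5.95 and -6.88) and Pou4f2 (-5.76 and -6.96). Nhlh2 was lower by a log2 fold change of -6.81 (adjusted p = 0.032), with adjusted p from 0.0502 to 0.081 without each control or orJ_mi library in turn, 0.0554 without a filter, and a change of -8.50 without orJ_mi 1.

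**Figure D3:**
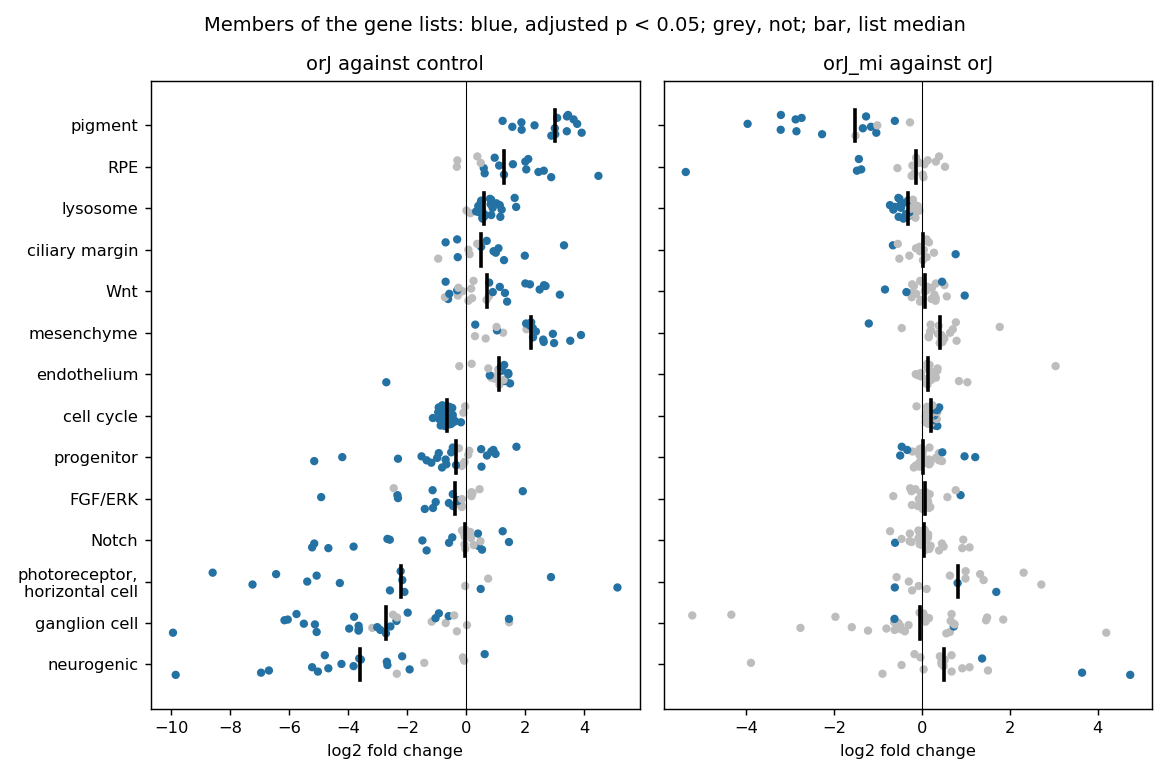
Log2 fold changes of the members of gene lists in orJ against control and in orJ_mi against orJ, with 1 point per gene, blue where the gene was called and grey where it was not, and a bar at the list median. All 15 pigment genes were called higher in orJ, and 12 of them lower in orJ_mi against orJ.

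The last comparison asks whether the mi allele moved genes back toward their control level. The return of a list was the share of its log2 change in orJ that orJ_mi reversed, over its members weighted by the squared change. The orJ libraries were divided so that the comparisons shared none, and the return is given as the mean and range over the 6 divisions. It was 68.8% for pigment genes (63% to 74.7%), 44.4% for the lysosome genes linked to Mitf and its relatives (37.8% to 51.4%) and 37% for pigment epithelium genes (32.1% to 43.1%, over 18 members, since the expression filter depends on group size and kept 1 more in these fits). For cell cycle genes it was 33.5% (23.9% to 44%), for neurogenic genes 27.9% (5.95% to 50.9%), for photoreceptor, horizontal and amacrine genes 22% (19.2% to 25.3%) and for progenitor genes 19% (11.8% to 26.8%). Notch genes returned by 15.5% (7.34% to 25.5%) and FGF genes by 12.1% (5.54% to 20.6%), and the range included 0 for ganglion cell genes (12.2%, -16.8% to 42.6%), ciliary margin genes (8.5%, -0.412% to 16.5%) and Wnt genes (-0.403%, -15.1% to 17.5%). The ranges cover the division of the orJ libraries only, not the spread of control and orJ_mi libraries. Library orJ 4 stood apart in mean log2 CPM of the neurogenic list (2.64, others 0.817 to 1.05) and the ganglion cell list (2.8, others -0.103 to 0.339). How far its place in a division sets these ranges was not tested. Over all genes called in orJ with at least a 2-fold change, the return was 17.6% (11.6% to 25.8%). On this log2 scale, the return of a gene that is very low in orJ is larger than the share of its level regained. Atoh7, for example, stood at 697, 0.771 and 19.8 CPM in control, orJ and orJ_mi.

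Of the 6806 genes changed in orJ against control, 958 changed again in the opposite direction in orJ_mi against orJ, 648 of them higher in orJ and then lower and 310 lower and then higher. Another 15 changed again in the same direction, among them Lmo3, at 0.916, 17.2 and 30.6 CPM in control, orJ and orJ_mi (chosen after its values were seen for these steps). The opposite changes made up 92.2% of the 1039 genes called in orJ_mi against orJ, and 66 of those genes were not called in orJ against control. The orJ libraries enter both comparisons, which raises opposite changes by chance. Simulated groups without effects gave a mean of 0.1 opposite genes and at most 1, and simulations that kept the orJ effect gave a mean of 0.2 and at most 2. Independent lists of these sizes would share 140.1 genes higher then lower and 65.24 lower then higher, and 74.57 and 122.5 in the same directions. With the orJ libraries divided so that the comparisons shared none, 349 to 527 genes changed in opposite directions (mean 452.7) and 3 to 14 in the same direction (mean 8.33) over the 6 divisions. The log2 fold changes of the comparisons had a correlation across genes of -0.4761, where genes are not independent replicates, and -0.366 to -0.202 with divided orJ libraries. The mean correlation was -0.5057 in unchanged simulated groups and -0.1534 in simulations that kept the orJ effect with no effect of the mi allele. The covariance of the fold changes was -0.1711, against -0.03883 in unchanged simulated groups, a difference of -0.1322, and -0.03803 in simulations that kept the orJ effect. The opposite count was 607 without orJ 2 and 629 without orJ 1, and the same-direction count was 6 without orJ 2 and 8 without orJ 1 or orJ_mi 3. With the Y-linked covariate the counts were 603 opposite and 7 in the same direction, at an adjusted p under 0.01 477 and 4, and tested against a 1.5-fold change 124 and 1. The same-direction count was 27 with DESeq2 and 26 without the 4 libraries that stood apart.

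**Figure D4:**
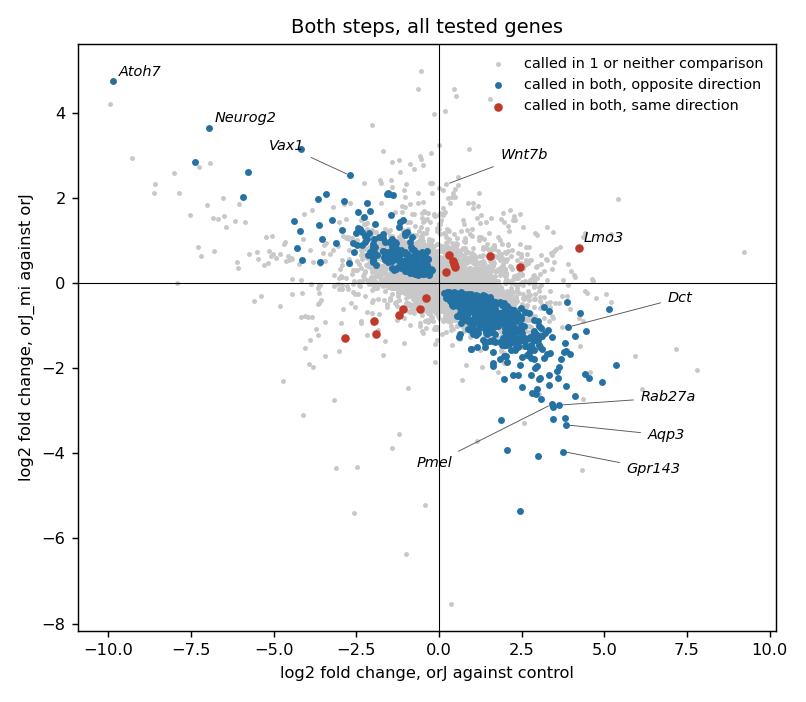
Log2 fold change of orJ against control on the horizontal axis and of orJ_mi against orJ on the vertical axis, with 1 point per tested gene, blue for the 958 genes called in both with opposite signs, red for the 15 called in both with the same sign and grey for the rest. Rab27a lay at 3.64 and -2.87 and Vax2 at -1.52 and 0.97.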

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

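The tests of the mesenchyme pattern and of the Atoh7 and Neurog2 pattern were chosen after the values they measure had been seen, while the splits of the libraries and the positions near the mutated genes had their predictions written before the results were seen.

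By Dixon's gap test, a library lay far from the other 3 in 53 of 564 groups of 4 libraries. For normal, independent values chance gives about 1 in 20 groups, here 28.2. The groups were library measures, list means and named genes over the same libraries, so they were not independent. Some genes stood near 0 CPM, where values are skewed, so 53 against 28.2 is not a tested excess. Of the 53, 19 were in orJ_mi 1, 14 in orJ 4, 6 in control 4 and 4 in orJ_mi 4. In control 1, Rax was at 386 CPM (others 254 to 275), Hes6 at 248 (163 to 177) and the sex-linked list at a mean log2 CPM of 5.68 (4.43 to 4.55). In control 3, Bmp4 was at 7.79 CPM (11.1 to 11.3) and Gsx2 at 0.258 (0.884 to 0.942). In control 4, Gas1 was at 194 CPM (148 to 149), Slc2a1 at 819 (564 to 600), Pdk1 at 69.9 (43.4 to 47.7), Dusp1 at 127 (23.9 to 29.7), Tbx2 at 325 (238 to 249) and Isl1 at 29.1 (41.3 to 42.6).

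Among the orJ libraries, orJ 2 had Rxra at 91.8 CPM (85.1 to 85.7) and Col6a3 at 31.7 (4.18 to 7.15), and orJ 3 had Brinp1 at 13.3 (10.9 to 11.1) and Wfdc1 at 195 (160 to 165). In orJ 4 the mean log2 CPM was 2.64 for the neurogenic list (0.817 to 1.05), 2.8 for the ganglion cell list (-0.103 to 0.339) and 4.6 for the Notch list (4.39 to 4.42). The same library had Pitx1 at 37.6 CPM (0.33 to 0.994), Neurog2 at 1.46 (0.613 to 0.715), Bmp2 at 7.08 (5.62 to 5.81), Vax1 at 3.15 (0.87 to 1.23), Eya1 at 42 (30.6 to 31.4) and Gata2 at 6.35 (1.14 to 1.49). Its neuronal genes were Nhlh2 at 11.1 CPM (0 in the others), Igfbpl1 at 2.67 (0 to 0.0732), Stmn2 at 26 (0.403 to 0.87), Ina at 15.9 (0.732 to 1.21) and Isl1 at 2.79 (0.466 to 0.769).

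Among the orJ_mi libraries, orJ_mi 3 had Stra6 at 251 CPM (276 to 280), and orJ_mi 4 had Eya1 at 18.8 (12.8 to 13.6), Cd63 at 114 (94.5 to 97.5), Bub1b at 151 (138 to 140) and Crx at 14.6 (9.79 to 10.6). In orJ_mi 1, neural genes were Atoh7 at 55.5 CPM (4.15 to 11), Gal at 0.33 (0 to 0.0359), Onecut1 at 1.29 (0.137 to 0.288), Mir124a-1hg at 1.11 (0.0719 to 0.247), Igfbpl1 at 1.32 (0.103 to 0.247), Stmn2 at 2.22 (0.431 to 0.658), Isl1 at 3.45 (1.03 to 1.3) and Grin2c at 1.95 (0.611 to 0.753). Its genes of other tissues were Pitx2 at 62.4 CPM (8.98 to 15.5), Col1a1 at 87.2 (9.96 to 20), Foxc1 at 59.6 (7.44 to 14.3), Col6a3 at 50.3 (2.46 to 8.92), Irx1 at 38.8 (2.08 to 5.63), Emx2 at 7.61 (0.826 to 1.69), Krt18 at 30.8 (16.6 to 18.2) and Hsf4 at 2.01 (0.992 to 1.08). The remaining genes were Pax2 at 76 CPM (83.9 to 84.2), Crabp1 at 44.3 (26.6 to 27.4) and Rlbp1 at 15.6 (7.65 to 8.28).

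Periocular mesenchyme genes were higher in orJ and orJ_mi than in control, by 1.97 and 2.02 log2 units of the list mean. A lower share of retinal cells alone, which raises markers of every other tissue alike, cannot be told apart from a change of the mesenchyme: a test of whether 8 lists of other tissues moved apart beyond a common shift gave an exact permutation p of 0.114 in orJ and 0.0571 in orJ_mi, and 0.0857 in either over members with at least 1 CPM. It replaced a test on the macrophage list alone, and singly the mesenchyme mean rose in orJ above the erythroid, macrophage and neural crest means by 1.24, 1.7 and 1.18 (exact permutation test, two-sided p = 0.0286 each, the smallest that 4 against 4 libraries can give, 0.0667 adjusted over the lists) and above the endothelium, surface ectoderm, diencephalon and lens means by 0.933, 0.424, 1.71 and 2.7 (p from 0.0571 to 0.486). Carry-over of neighbouring tissue, which dissection per the labels would remove, may contribute. The 19 genes varied together within groups (median correlation across gene pairs 0.747, against 0.00381 for random lists and 0.0909 at their 95th percentile, and 0.303 without orJ_mi 1 and orJ 2). Markers of a tissue vary together whatever changes its share, so this correlation cannot tell carry-over from a change of the mesenchyme. The lens, endothelium and erythroid lists also had high estimated correlations in camera (0.794, 0.702 and 0.715 in orJ against control). Col1a1 and Col3a1 stood at 24 and 54.2 CPM in orJ and 32.4 and 60.5 in orJ_mi, 15 of the 19 genes reached 1 CPM in control retina, 0 of them shared with other lists, and a change of the mesenchyme with the genotype stays open, untested.

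Atoh7 and Neurog2 were higher in orJ_mi than in orJ. Control retina RNA in the orJ_mi libraries would bring both at the same share of their control level, but the Neurog2 share was 2.7 times the Atoh7 share in orJ_mi 1 and 5.36, 5.56 and 4.39 times in the others, against 0.797 to 1.1 in control libraries. That test replaced an earlier one over 14 genes low in orJ, whose shares ran from 0.355% to 9.9% with a median of 2.32%. In it 2 genes (14.3%) lay beyond a 2-fold range around the median by more than counting error. They were Neurog2 (9.9%) and Fos (0.355%), which was high in control 4 alone, while Atoh7 (3.03%) lay within the range. The ratio rests on Neurog2, which the earlier test had set apart, so control RNA stays open for the Atoh7 rise. Library orJ_mi 1 alone did not account for the pattern, since without it Neurog2 changed by 2.90 (SE 0.331, adjusted p = 0.000553) and Atoh7 by 3.40 (SE 0.391, adjusted p = 0.000941, edgeR's quasi-likelihood test). An effect of the mi allele on neurogenic genes may explain the rest, as a hypothesis found and tested on the same libraries.

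For the counts of changed genes, the 8 libraries of each comparison were split into 4 and 4 in all 35 ways. Only 1 of the 35 splits, the real split, called as many genes, the smallest share this test can give. Every other split mixes the compared groups, which widens the spread within each set of 4, so the low counts there do not exclude chance. The splits also cannot tell genotype from another difference between the groups. Fitted on those 8 libraries alone, the real split called 6221 genes in orJ against control (highest other split 8), 1608 in orJ_mi against orJ (highest other 2) and 3682 in orJ_mi against control (highest other 1). Strain background linked to the mutated genes did not account for most of the calls, since 2.6% of the 1039 genes called in orJ_mi against orJ lay within 20 Mb of Mitf and 1.47% of the 6806 called in orJ against control lay within 20 Mb of Vsx2. Among tested genes the shares were 1.56% and 1.72%, so calls near Mitf were more frequent (Fisher's exact test, two-sided p = 0.00918), and for those 27 genes linked variants may contribute. Calls near Vsx2 were less frequent (p = 0.043, Fisher's exact test).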

How the results depend on the processing

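The covariate of Y-linked genes and the fit without control 1, control 4, orJ 4 and orJ_mi 1 were chosen after seeing the data, and the other alternatives were planned. The covariate mainly sets orJ 1 and orJ 3, with almost no Y-linked RNA, apart from the other libraries, so it leaves less information on the orJ group. Among the 245 gene results and 38 list calls, no result called in either fit changed direction under the alternatives run for it. Direction was not compared for genes that neither fit called, nor for lists with an estimated correlation. Median-of-ratios scaling, limma-voom, both other filters on low counts, the library number set as a block and the non-robust spread kept each count of changed genes within 1.5 times its value. Tested against a 1.5-fold change, which by construction passes fewer genes, 1749 genes changed in orJ against control (1159 higher, 590 lower), 127 in orJ_mi against orJ (19 higher, 108 lower) and 860 in orJ_mi against control (526 higher, 334 lower), and 124 opposite and 1 same-direction gene made the return. At an adjusted p under 0.01 there were 509 genes in orJ_mi against orJ (145 higher, 364 lower), 2668 in orJ_mi against control (1472 higher, 1196 lower), and 477 opposite and 4 same-direction genes. With only the 2 groups compared, 1608 genes changed in orJ_mi against orJ, 667 of them higher. With the Y-linked covariate 635 changed, 182 of them higher, and 603 opposite and 7 same-direction genes made the return. Without the 4 libraries 1573 changed, 669 of them higher, with 26 same-direction genes, and 916 of the 1039 genes kept their call and direction. DESeq2 called 654 genes higher in orJ_mi than in orJ and 27 same-direction genes. For these fits the cause was not tested.

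Leaving out each library, orJ_mi against orJ ranged from 649 genes (without orJ 2) to 1509 (without control 1), those higher from 193 (without orJ 1) to 599 (without control 1) and those lower from 450 (without orJ 2) to 910 (without control 1). The opposite changes ranged from 607 (without orJ 2) to 1380 (without control 1) and the same-direction changes from 6 (without orJ 2) to 20. With the orJ libraries divided, 349 to 527 genes changed in opposite directions and at least 3 in the same direction, from smaller groups. The causes of the leave-one-out ranges were not tested.

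The replicate numbers were not taken to pair the libraries, since the 12 same-numbered pairs had correlations of -0.212 to 0.16. All 4 control libraries correlated best with their own number among the orJ libraries, but only 1 of the 12 libraries did so in both other groups. With a replicate block, 6637, 937 and 4262 genes changed in the 3 comparisons, 6420, 872 and 4135 of them shared with the fits without it, and all 38 list calls were kept. Libraries of the same library number set deviated together little (mean correlation 0.058, against -0.059 between sets).

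Of 245 gene results, limma-voom ended the call of 17, no filter 14, the replicate block 9, the library set block 2, only the 2 groups compared 8, the Y-linked covariate 17, the fit without the 4 libraries 17, and leaving out single libraries 31. Median-of-ratios scaling, DESeq2 and the stricter filter ended none of those with a value. DESeq2 and the fit without the 4 libraries began 3 calls each, limma-voom, both blocks and only the 2 groups compared 2 each, and median-of-ratios scaling, the stricter filter and the Y-linked covariate 1 each. Of 38 list calls, 17 held with an estimated correlation, 36 with fry, 36 without the 4 libraries and 35 over all libraries left out singly. Scaling moved the median log2 fold change of all genes by little (-0.00287 and -0.0178 in orJ against control), and the share of calls that were higher was 53.3% and 50.3% there, and 34.7% and 38.8% in orJ_mi against orJ. In orJ against control, simulated changes of 1.5-fold were recovered at 44.8% and those of 4-fold at 89.4%, at the depth, spread and number of these libraries, whose separate effects were not tested.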

Other observations

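The genes named here were chosen after their values were seen, apart from Wnt7b and Neb, which the rule for named genes took in orJ_mi against orJ.

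Of the 1039 genes called in orJ_mi against orJ, 66 were not called in orJ against control, and whether the comparisons differ for a gene was not tested. The signalling ligand Wnt7b stood at 7.97 ± 0.649 CPM in control, 9.36 ± 4.5 in orJ and 46.1 ± 6.37 in orJ_mi (SD, n = 4), uncertain where it overlaps AU022754, and the axon guidance ligand Slit3 at 4.6, 6.37 and 14 CPM (1.14 in orJ_mi against orJ, SE 0.192, adjusted p = 0.00164). Cyclin D2, Ccnd2, stood at 207, 224 and 382 CPM (0.77, SE 0.119, adjusted p = 0.00103), and the chemokine Cx3cl1 at 4.76, 4.74 and 12.3 CPM (1.38, SE 0.255, adjusted p = 0.00436). Nckap5 went the other way, at 17.6, 16.7 and 8.17 CPM (-1.03, SE 0.138, adjusted p = 0.000265). Of these, Ccnd2 lies on the chromosome of Mitf (chromosome 6, 127125162 to 127152193).

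Among the 15 genes that changed in the same direction at both steps, 8 were higher at each and 7 lower. Fgd3, an exchange factor for small GTPases, stood at 11.8, 64.5 and 83 CPM in control, orJ and orJ_mi, the Wnt and FGF antagonist Shisa2 at 434, 604 and 776 CPM, and the glutamate receptor subunit Gria1 at 11.1, 13.7 and 21.4 CPM. Lower at both were Ankrd33b (log2 fold changes -2.85 and -1.29), the transcription factor Npas1 (-1.22 and -0.75) and the Notch effector Hey1 (34.2, 22.9 and 15 CPM). By edgeR's quasi-likelihood test the second step of Hey1 was -0.61 (SE 0.158, adjusted p = 0.0353) and that of Shisa2 0.36 (SE 0.072, adjusted p = 0.00592).

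Some further genes are given as values per library. The muscle gene Neb was at 5.03, 1.85, 17.2 and 5.75 CPM in orJ_mi 1 to 4, the muscle gene Ttn at 6.23, 0.479, 40.7 and 9.31, and the muscle regulator Myog at 5.6, 0.274, 20.8 and 5.71. All were highest in orJ_mi 3 and belonged to the genes called in orJ_mi against orJ only. By edgeR's quasi-likelihood test Ttn changed by 4.55 (SE 1.11, adjusted p = 0.04525) and Myog by 4.31 (SE 1.09, adjusted p = 0.04977). The lens crystallin Cryaa ranged from 3.77 CPM in orJ 2 to 853 in orJ_mi 1. Xist and Ddx3y were both present in control 1 (356 and 34.1 CPM), orJ 4 (269 and 48), orJ_mi 1 (255 and 50.8), orJ_mi 2 (1367 and 18.2) and orJ_mi 4 (549 and 40). Libraries orJ 1 and orJ 3 had Xist at 1177 and 1653 CPM and Ddx3y at 0.0311 and 0.11, and the other 5 libraries had Xist at 0.589 to 1.12 CPM.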
